A study of Arabidopsis thaliana with 16 samples.

How the data were processed

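RNA was sequenced from whole seedlings of Arabidopsis thaliana in 2 experiments with 16 libraries in 8 groups of 2. In the first, wild-type seedlings grown in cycles of 12 h of light and 12 h of dark received 40 mg/L of a compound that the labels call Aza and do not spell out, or a mock treatment, and were collected on the following day, 1 h (ZT1) or 13 h (ZT13) after lights on. In the second, Col-0 and ddcc, a quadruple mutant of the DNA methyltransferase genes DRM1, DRM2, CMT2 and CMT3, were moved to constant light and collected after 24 h (LL24) or 36 h (LL36). The libraries were made from total RNA. The labels give no batch, date or order of sequencing, so batches were not analysed here.

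The deposited values are FPKM, which are fragments scaled to gene length and to the mapped fragments of the library, computed by the authors with 1 column per library. Per the submitters' processing notes, HISAT2 and DESeq2 were used with the TAIR10 genome. Their versions, the read counter and any filter are not given in the sources used here. The tables differ in content. The Aza table has 21026 features, of which 20948 are protein coding, and holds no chloroplast gene. The ddcc table has 34533 features, among them 5103 non-coding RNAs, 1429 small RNA features that carry other labels than a locus, and 271 features with only a running number, here called unnamed. Gene names came from the TAIR10.1 annotation, to which 20951 and 32548 of the features matched by locus. Coordinates are not printed, since that release is not the one in the notes. Features in both tables number 20950, and the experiments were fitted apart because their tables were scaled apart.

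No read counts are in the tables, so depth was estimated from the steps between low FPKM values. In the ddcc table, 68.5% of the 43159 values that come to under 50 fragments were whole numbers within 0.02 fragments, where even spread gives 4%, at depths of 14.2 to 23.2 M fragments per library. In the Aza table the values are rounded to 2 decimals and the estimate, 16.9 to 24.8 M fragments, is less certain. Replicates correlated across genes with Pearson's r from 0.982 to 0.993; genes are not independent replicates.

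FPKM were analysed as log2(FPKM + 1) with limma 3.58.1 in R 4.3.3 (lmFit, and eBayes with a trend), after tables were read with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6. Figures were drawn with matplotlib 3.10.9. Genes with a mean of at least 0.5 FPKM over the 8 libraries of an experiment were tested, 18688 for Aza and 19825 for ddcc. All 4 groups of an experiment entered 1 fit with 4 residual degrees of freedom, to which the fit added prior degrees of freedom of 4.97 (Aza) and 6.17 (ddcc). Changes are differences of log2(FPKM + 1), which understate folds of genes with low values. A gene was called at a Benjamini-Hochberg adjusted p below 0.05, two-sided. The contrasts were treatment or genotype at each time, their mean over both times, the difference between times, and time in the controls. The p-values measure only the spread between these samples, 2 per group.

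The text names genes by a rule: the mutated genes, SDC and ZTL; per comparison at a time the 8 largest rises and the 8 largest falls among called genes whose groups do not overlap and whose higher group averages at least 2 FPKM; up to 4 called members of each list, or else the 2 most abundant; and 9 clock genes for time of day. Some are left out for length. The contrasts, tests, alternatives, this rule and 16 lists of genes were chosen before the data were examined. The adjustment over the members of a list alone, given beside the calls over all genes, was not part of that plan. The lists are morning clock, evening clock, clock photoreceptors, genes silenced by methylation, DNA methylation machinery, DNA damage response, S phase, G2 to M phase, hypocotyl growth, light harvesting, flavonoids, defence, cold and heat response, flowering time, root markers and seed markers. Dusk genes and dawn genes, called higher or lower at the later time in the control libraries of the other experiment, make 18 lists. Lists were tested with camera of limma at a preset correlation of 0.01, adjusted over 108 tests, and again with an estimated correlation; fry tested lists against no change. A list of transposable element genes could not be made from these tables. Overlaps used Fisher's exact test, two-sided.

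The procedure was tested on simulated data. Changed genes were drawn from those with a mean of at least 2 FPKM, and the noise was independent between libraries. Recovery of genes with lower values was therefore not measured. Of 100 genes changed 2-fold, 88% were recovered for Aza against Mock at ZT1 and 70% for ddcc against Col-0 at LL24; of 100 changed 4-fold, 99% were recovered in each. False calls made up 6.97% of 201 calls and 8.65% of 185 calls, above the nominal 5%. The alternatives were a pseudocount of 0.1, no filter, a mean of at least 5 FPKM, quantile normalization, a block for replicate numbers, only the groups compared, a change of at least 2-fold, and leaving out each library in turn. Their effects are in the closing section. Members of families with near-identical sequences (LHCB1 and LHCB2, SAUR19 to SAUR24, the H3.1 histones, and the gene pairs AT5G46900 and AT5G46890 or AT4G12510 and AT4G12520) can share reads, which FPKM alone cannot resolve.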

Results

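The data are FPKM from 16 libraries of whole seedlings, 2 per group. Aza and Mock were compared at ZT1 and ZT13, and ddcc and Col-0 at LL24 and LL36. The estimated depth was 16.9 to 24.8 M fragments per library in the Aza experiment and 14.2 to 23.2 M in the ddcc experiment. The series asks which circadian genes respond to cytosine methylation and how the imprinted gene SDC acts on the clock and on the hypocotyl.

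Aza against Mock at ZT1 asks what the compound changes 1 h after lights on. SDC, an F-box gene silenced by methylation, rose by 2.51 ± 0.15 on the log2 scale (SE, 2 libraries per group, adjusted p = 0.000173), from 0.64 and 0.31 FPKM in Mock to 7.81 and 6.93 with Aza. The cell-cycle inhibitor SMR7 rose most, by 3.55 ± 0.31 (adjusted p = 0.00137), from a mean of 1.69 to 30.1 FPKM. The repair gene BRCA1 rose by 2.45 ± 0.18 (adjusted p = 0.000586). KNOLLE, which acts in cell division, fell by 1.25 ± 0.10 (adjusted p = 0.00111), from 37.5 to 15.2 FPKM.

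At ZT1, 109 of 18688 genes were higher and 136 lower with Aza. Of the DNA damage response genes, 13 of 22 rose and 0 fell; adjusted over the list alone, 18 rose. The list moved up (median 0.94, camera adjusted p = 1.95e-30; adjusted p = 0.144 with an estimated correlation). Among the G2 to M phase genes 12 of 16 fell, or 15 adjusted over the list alone (median -0.73, adjusted p = 6.17e-27), and this call held with an estimated correlation (adjusted p = 0.0305). Of 5 tested genes silenced by methylation, SDC, QQS and FWA rose on either adjustment (list adjusted p = 3.38e-05, and 0.144 with an estimated correlation). The list has 20 members, most of them not tested. Members silent in Mock, such as FWA, pass the filter only where Aza raises them. The p-values of this list, here and below, therefore lean on members that the outcome brought in. The glycine-rich RNA-binding gene GRP7, a clock output, fell by 1.73 ± 0.21 (adjusted p = 0.00806), from 255 to 77.9 FPKM. The root genes AGP13 and AGP30 fell, with changes of -2.27 and -2.18, and RSL4 fell from a mean of 2.62 to 0.805 FPKM.

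The remaining lists at ZT1 moved less. No defence gene was called over all genes and 2 of 16 rose adjusted over the list alone (median 0.17, adjusted p = 0.00486; adjusted p = 0.382 with an estimated correlation). Of 17 root markers only RSL4 fell, on either adjustment (median -0.13, adjusted p = 0.00243; adjusted p = 0.515 with an estimated correlation); the list gave 0.0809 without Aza ZT1 replicate 1. RNR1 alone rose among the S phase genes (list adjusted p = 0.892). The other lists were not called. Their adjusted p was 0.157 for DNA methylation machinery, 0.269 for evening clock and for dawn genes (the latter 0.0282 with quantile normalization), 0.339 for clock photoreceptors, 0.534 for flowering time, 0.628 for morning clock, 0.675 for light harvesting and for flavonoids, 0.881 for dusk genes, 0.892 for hypocotyl growth, 0.896 for cold and heat response and 0.973 for seed markers. Mean and median differed in sign for evening clock (-0.17 and 0.07), hypocotyl growth (-0.01 and 0.03) and dusk genes (-0.01 and 0.04); for seed markers both were negative and the test pointed up.

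The core clock did not pass the threshold at ZT1: CCA1 changed by 0.04 ± 0.24 (adjusted p = 0.984), LHY by 0.12 ± 0.27 (adjusted p = 0.941) and TOC1 by 0.06 ± 0.18 (adjusted p = 0.964). ZTL changed by -0.05 ± 0.15 (adjusted p = 0.967). This comparison rests on each of its libraries. The 109 higher and 136 lower genes became 34 and 10 without Mock ZT1 replicate 1, 23 and 15 without Mock ZT1 replicate 2, 20 and 6 without Aza ZT1 replicate 1 and 26 and 27 without Aza ZT1 replicate 2, with more lower than higher genes in 1 of these 4 fits. Of 27 named calls, 11 held in every such fit, SDC, SMR7, BRCA1 and KNOLLE among them; those of FWA, QQS, RNR1, AGP13, AGP30 and RSL4 ended without any 1 of the 4. The call of GRP7 ended without any 1 of 3 libraries, Mock ZT1 replicate 1 among them.

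Aza against Mock at ZT13 asks the same 12 h later. SDC rose by 3.61 ± 0.15 (SE, 2 libraries per group, adjusted p = 1.73e-05), from 0.08 and 0.20 to 12.5 and 13.2 FPKM. SMR7 rose by 4.84 ± 0.31 (adjusted p = 9.77e-05) and the pathogenesis-related gene PR2 by 4.19 ± 0.52 (adjusted p = 0.00289), the latter to 57.9 and 14.3 FPKM. The Casparian strip gene CASP1 fell by 1.82 ± 0.20 (adjusted p = 0.00193). The demethylase gene ROS1 fell from a mean of 9.40 to 3.75 FPKM (adjusted p = 0.0108), and reached an adjusted p of 0.0775 without Aza ZT13 replicate 2.

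At ZT13, 447 genes were higher and 511 lower. DNA damage response genes rose in 15 of 22 cases and 0 fell, with 18 adjusted over the list alone (median 1.12, adjusted p = 3.88e-22; adjusted p = 0.144 with an estimated correlation). XRI1 rose by 2.66 ± 0.12 (adjusted p = 1.73e-05). G2 to M phase genes fell in 11 of 16 cases, 14 adjusted over the list alone (median -0.84, adjusted p = 4.71e-14; adjusted p = 0.0557 with an estimated correlation). Defence genes rose in 7 of 16 cases, 10 adjusted over the list alone (median 0.74, adjusted p = 1.53e-08; adjusted p = 0.144 with an estimated correlation). SDC, QQS and FWA rose again on either adjustment (list adjusted p = 0.000135; adjusted p = 0.156 with an estimated correlation). QQS, an orphan gene of starch metabolism, rose by 2.50 ± 0.15 (adjusted p = 9.77e-05). Of 17 root markers 5 fell and NRT2.1 rose, or 9 and 1 adjusted over the list alone (median -0.45, adjusted p = 1.16e-06; adjusted p = 0.218 with an estimated correlation).

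Weaker list calls at ZT13 each ended without some library. By fry, the unadjusted p was 0.0802 for clock photoreceptors, 0.121 for light harvesting and 0.297 for flavonoids. PHYA and PHOT1 fell among 11 photoreceptor genes, on either adjustment (median -0.20, adjusted p = 0.0335; adjusted p = 0.883 with an estimated correlation); the list gave 0.354 without Mock ZT13 replicate 2 and 0.177 without Aza ZT13 replicate 1. No light harvesting gene was called on either adjustment (median 0.25, adjusted p = 0.0109; adjusted p = 0.883 with an estimated correlation), and the list gave 0.243 without Mock ZT13 replicate 2 and 0.367 without Aza ZT13 replicate 2. The flavonoid list had no called gene either (median 0.31, adjusted p = 0.0418; adjusted p = 0.883 with an estimated correlation); it gave 0.597 without Mock ZT13 replicate 1, 0.244 without Aza ZT13 replicate 2, 0.0826 with quantile normalization and 0.0722 without a filter. Lists not called were DNA methylation machinery (adjusted p = 0.0626), dawn genes (0.0638; 0.0247 with the replicate block), flowering time (0.151), dusk genes (0.206), cold and heat response (0.244), seed markers (0.738), morning clock (0.741), S phase (0.786), evening clock (0.790) and hypocotyl growth (0.838).

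CCA1 and LHY stood near their daily minimum at ZT13, and changed by 0.50 ± 0.24 (adjusted p = 0.278) and 0.72 ± 0.27 (adjusted p = 0.179). ZTL changed by -0.26 ± 0.15 (adjusted p = 0.367). The 447 higher and 511 lower genes became 233 and 228 without Mock ZT13 replicate 1, 454 and 444 without Mock ZT13 replicate 2, 262 and 268 without Aza ZT13 replicate 1 and 193 and 180 without Aza ZT13 replicate 2. Of 37 named calls, 30 held in all 8 such fits. The call of PHYA ended in 8 of them, those of PHOT1 and MCM7 in 7, and that of NRT2.1 in 3. That of RNR1 ended in 2, and those of ROS1 and AGP30 in 1. With only the groups compared, the limma calls of PHYA (adjusted p = 0.185), PHOT1 (0.141), MCM7 (0.149), RNR1 (0.0794) and ROS1 (0.0572) ended too.

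Over both times, Aza raised 538 genes and lowered 657. Of the genes higher at ZT1, 94 were also higher at ZT13, against 2.61 expected, and 113 were lower at both, against 3.72. The expected counts take the calls as independent, but both times share each gene's estimate of spread and the filter. Part of the excess can come from that, which was not tested. Of 996 genes called at either time, 925 changed in the same direction at both. The difference between the times reached the threshold for 0 genes with limma (smallest adjusted p = 0.335), while 1358 had an unadjusted p below 0.05. GRP7 is an instance: its changes at the 2 times differed by 1.82 ± 0.30, which did not pass over all genes (adjusted p = 0.428) but did over the 12 evening clock genes alone (adjusted p = 0.00245). Over both times the 1195 calls became 685, 689, 666 and 677 without Mock ZT1 replicate 1, Mock ZT1 replicate 2, Aza ZT1 replicate 1 and Aza ZT1 replicate 2.

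**Figure D1:**
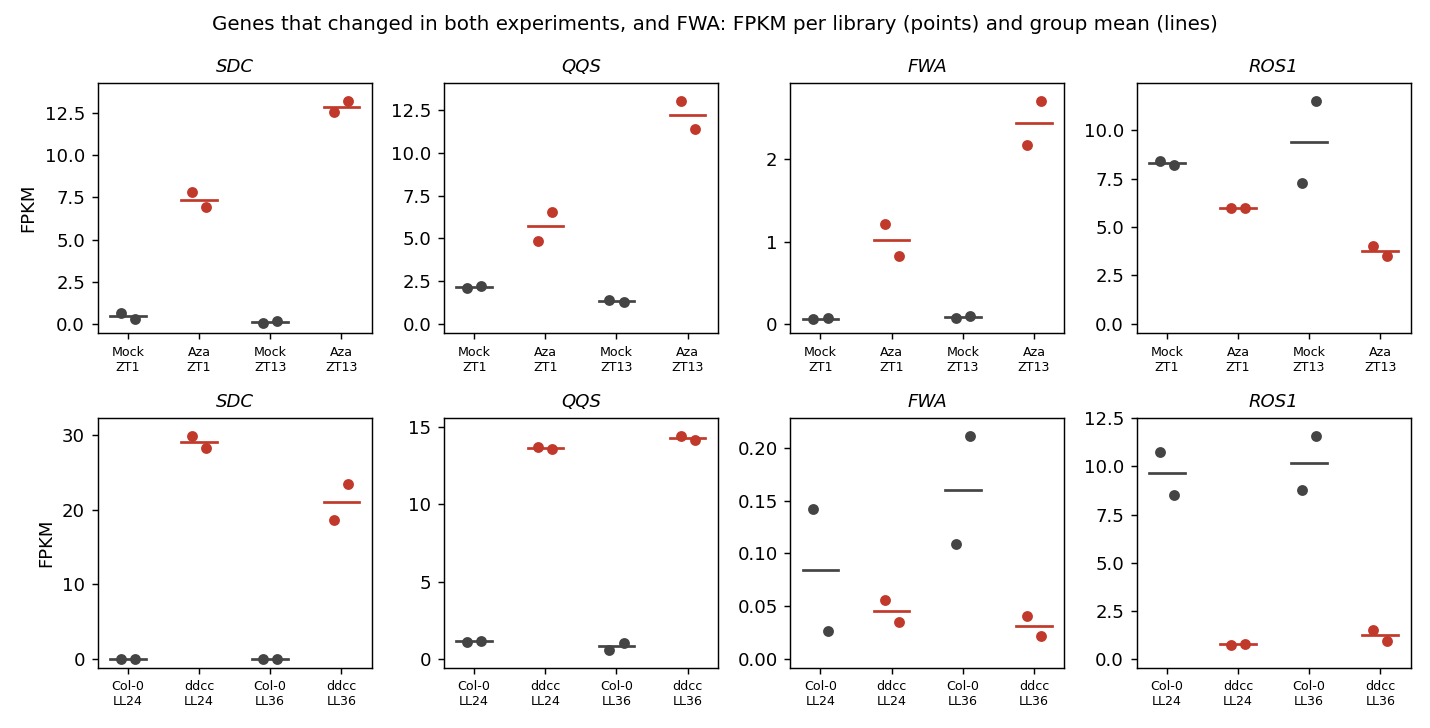
FPKM of SDC, QQS, FWA and ROS1 in each library (points; lines are group means), with Aza and Mock in the upper panels and ddcc and Col-0 in the lower. SDC was listed at 0 FPKM in all Col-0 libraries and FWA stayed low in ddcc.

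**Figure D2:**
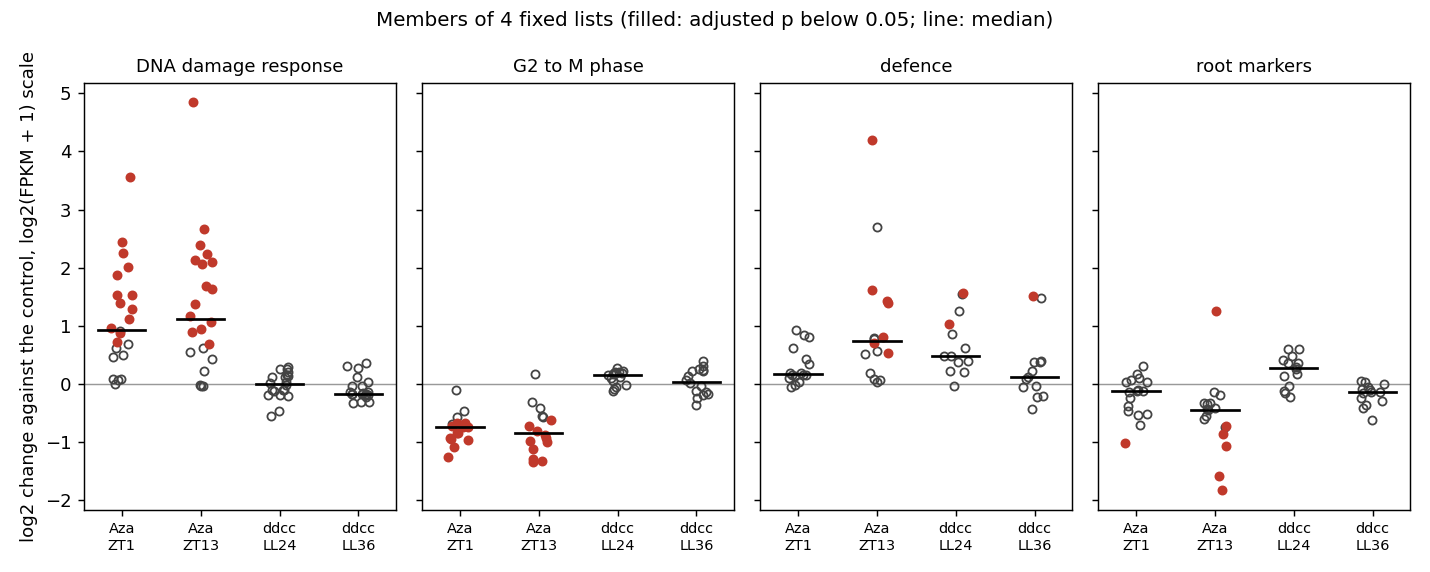
Changes on the log2(FPKM + 1) scale of the members of 4 lists in the 4 comparisons at a time, with filled points for called genes and lines at the medians. The DNA damage response and G2 to M phase genes moved apart with Aza, with medians of 0.94 and -0.73 at ZT1 (adjusted p = 0.144 and 0.0305 with an estimated correlation).

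Time of day in Mock serves as a check of the labels. LHY fell by 7.53 ± 0.27 from ZT1 to ZT13 (SE, 2 libraries per group, adjusted p = 2.07e-07), from 284 to 0.555 FPKM, and CCA1 fell by 6.87 ± 0.24 (adjusted p = 1.74e-07). TOC1 rose by 2.50 ± 0.18 (adjusted p = 9.39e-06) and ELF4 by 4.49 ± 0.16 (adjusted p = 1.96e-07). PRR7 changed by -0.01 ± 0.31 (adjusted p = 0.982). GI fell by 1.14 ± 0.25 (adjusted p = 0.00674), and reached 0.0513 without Mock ZT1 replicate 2. In all, 5479 genes were higher and 1961 lower at ZT13. That split depends on scaling: quantile normalization gave 2953 and 2883, and moved the median of all genes from 0.20 to 0.004. Without Mock ZT1 replicate 2, 4751 genes were called.

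ddcc against Col-0 at LL24 asks what loss of the 4 methyltransferases changes after 24 h in constant light. The mutated genes come first. CMT3 fell from 8.74 and 10.1 FPKM in the Col-0 libraries to 1.49 and 1.05 in ddcc (adjusted p = 0.00044). DRM2 fell by 1.11 ± 0.17 on the log2 scale (SE, 2 libraries per group, adjusted p = 0.00618). The call of DRM2 ended without any 1 of 3 libraries, Col-0 LL24 replicate 1 among them. CMT2 changed by -0.47 ± 0.19 (adjusted p = 0.334), and DRM1 stood near 0 FPKM in Col-0 and ddcc alike and was not tested. SDC rose by 4.91 ± 0.17 (adjusted p = 9.99e-08), listed at 0 in both Col-0 libraries.

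At LL24, 297 of 19825 features were higher and 69 lower. ENODL17, an early nodulin-like gene, fell by 5.84 ± 0.15 (adjusted p = 1.99e-08), from 56.8 and 60.6 FPKM to 0 and 0.0855. ROS1, whose promoter methylation keeps it active, fell by 2.59 ± 0.20 (adjusted p = 3.13e-05). QQS rose by 2.77 ± 0.17 (adjusted p = 4.87e-06), AT3G29639 by 5.89 ± 0.16 (adjusted p = 1.99e-08) and AT5G03090 by 5.37 ± 0.32 (adjusted p = 3.9e-06). The jasmonate-responsive storage gene VSP2 fell by 2.00 ± 0.15 (adjusted p = 3.02e-05). The expansin gene EXPA8 fell by 0.89 ± 0.13 (adjusted p = 0.00479). Its call ended without any 1 of 2 libraries, ddcc LL24 replicate 2 among them. By feature class, examined after the values were seen, 21 of 227 long non-coding and antisense RNAs were higher. Tested features were then restricted to those with a mean of at least 0.5 FPKM in Col-0 at LL24. Of these, 9 of 187 such RNAs were higher, against 109 of 18779 protein-coding genes (odds ratio 8.66, Fisher's exact test, adjusted p = 5.16e-06). The filter for testing averages all 8 libraries, so features low in Col-0 at LL36 can still enter through ddcc. Part of the odds ratio can come from that, which was not tested. Of 236 unnamed features 102 were higher; how these were defined is not given, and if reads of these libraries defined them, those silent in Col-0 enter through ddcc, so their share is not set against that of coding genes.

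By list at LL24, 2 of 4 tested genes silenced by methylation rose on either adjustment, SDC and QQS (list adjusted p = 0.000838, and 0.177 with an estimated correlation). SDC, listed at 0 in Col-0, was tested only because ddcc raised it, so this list leans on the outcome at both times. Of 36 genes of the methylation machinery, DRM2, CMT3 and ROS1 fell on either adjustment (median -0.08, adjusted p = 0.00063; adjusted p = 0.701 with an estimated correlation). The list holds mutated genes; without them, a test chosen after the data were seen, its 33 genes gave a median of -0.08 (adjusted p = 0.0177; adjusted p = 0.883 with an estimated correlation). WRKY70 and PAD3 rose among 13 defence genes, 6 adjusted over the list alone (median 0.49, adjusted p = 2.08e-05, and 0.233 with an estimated correlation). The limma call of WRKY70 ended with quantile normalization (0.0540), without a filter (0.0639) and with only the groups compared (0.0735). That of PAD3 ended without a filter (0.133), with a mean of at least 5 FPKM (0.0556) and with only the groups compared (0.0941). No evening clock gene was called and 1 of 12 fell adjusted over the list alone (median -0.34, adjusted p = 0.000109; adjusted p = 0.227 with an estimated correlation). EXPA8 and SAUR21 fell among 27 hypocotyl growth genes, 5 adjusted over the list alone (median -0.02, adjusted p = 0.025; adjusted p = 0.382 with an estimated correlation); the list gave 0.0946 without Col-0 LL24 replicate 1 and 0.199 with a mean of at least 5 FPKM. Lists not called were cold and heat response (adjusted p = 0.0626; 0.0408 with a pseudocount of 0.1, 0.0345 with a mean of at least 5 FPKM, 0.0271 with quantile normalization and 0.0330 with the replicate block), clock photoreceptors (0.0812), flowering time (0.0897), flavonoids (0.118), seed markers (0.135), root markers (0.155), morning clock (0.350), DNA damage response (0.350), light harvesting (0.394), S phase (0.701), dusk genes (0.701), G2 to M phase (0.741) and dawn genes (0.944). For S phase the mean of 0.04 was positive while the median and the test were negative; for dusk genes the test alone was negative.

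LHY changed by 0.54 ± 0.15 at LL24 (adjusted p = 0.135), CCA1 by 0.34 ± 0.20 (adjusted p = 0.535), TOC1 by -0.27 ± 0.16 (adjusted p = 0.538) and ZTL by -0.09 ± 0.13 (adjusted p = 0.82). The 297 higher and 69 lower features became 213 and 44 without Col-0 LL24 replicate 1, 213 and 41 without Col-0 LL24 replicate 2, 243 and 24 without ddcc LL24 replicate 1 and 177 and 20 without ddcc LL24 replicate 2. Of 22 named calls, 16 held in all 8 fits. The call of PAD3 ended in 7 of them, those of WRKY70 and AT1G14250 in 5, that of SAUR21 in 4, DRM2 in 3 and EXPA8 in 2. SAUR21 and PAD3 reached their highest adjusted p without ddcc LL24 replicate 2 and WRKY70 without Col-0 LL24 replicate 2.

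ddcc against Col-0 at LL36 asks the same 12 h later. CMT3 fell by 2.38 ± 0.24 (SE, 2 libraries per group, adjusted p = 0.000231) and DRM2 by 1.25 ± 0.17 (adjusted p = 0.0025), while CMT2 changed by -0.57 ± 0.19 (adjusted p = 0.295). SDC rose by 4.45 ± 0.17 (adjusted p = 1.64e-07) to 18.6 and 23.4 FPKM, again listed at 0 in Col-0. ENODL17 fell by 6.06 ± 0.15 (adjusted p = 1.36e-08), from 70.4 and 61.2 FPKM to libraries listed at 0. The auxin-response gene IAA29 fell by 1.22 ± 0.20 (adjusted p = 0.00812). Its call ended without any 1 of 4 libraries, Col-0 LL36 replicate 2 among them.

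At LL36, 243 features were higher and 98 lower. Of long non-coding and antisense RNAs 22 of 227 were higher, and of unnamed features 105 of 236. Among tested features with a mean of at least 0.5 FPKM in Col-0 at LL36 it was 6 of 190 such RNAs, against 50 of 18894 protein-coding genes (odds ratio 12.3, Fisher's exact test, adjusted p = 1.93e-05). Here features low in Col-0 at LL24 can likewise enter through ddcc. Hypocotyl growth genes fell in 2 of 27 cases, 10 adjusted over the list alone (median -0.33, adjusted p = 2.83e-06; adjusted p = 0.144 with an estimated correlation); with a mean of at least 5 FPKM the list was not called (0.0918). SDC and QQS rose and the methylation list was called (adjusted p = 0.000474; adjusted p = 0.177 with an estimated correlation); adjusted over the list alone 1 member also fell. LNK3 and LNK4, coactivators of the morning, fell among 14 morning clock genes, with 5 lower and 1 higher adjusted over the list alone (median -0.40, adjusted p = 0.00392; adjusted p = 0.701 with an estimated correlation); the list gave 0.137 without Col-0 LL36 replicate 2. LHCB2.1, LHCB1.1 and LHCB2.2 fell among 14 light harvesting genes, on either adjustment (median -0.13, adjusted p = 0.0124; adjusted p = 0.883 with an estimated correlation); the list gave 0.0842 without Col-0 LL36 replicate 1 and 0.417 without ddcc LL36 replicate 1. No flavonoid gene was called (median -0.27, adjusted p = 0.0115; adjusted p = 0.883 with an estimated correlation), and that list changed direction without Col-0 LL36 replicate 1 (0.828) and gave 0.0583 without ddcc LL36 replicate 1. WRKY70 rose alone among 13 defence genes, on either adjustment (median 0.12, adjusted p = 0.028; adjusted p = 0.701 with an estimated correlation); the list gave 0.185 without Col-0 LL36 replicate 2, 0.137 without ddcc LL36 replicate 1, 0.0722 without a filter and 0.496 with a mean of at least 5 FPKM.

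DRM2, CMT3 and ROS1 fell again at LL36, without a call for the machinery list (adjusted p = 0.0885; 0.540 without the mutated genes, and 0.0132 with them and a mean of at least 5 FPKM). The other lists not called were root markers (0.215), S phase (0.497), G2 to M phase (0.616), DNA damage response (0.699), clock photoreceptors (0.741), dawn genes (0.741), cold and heat response (0.815), flowering time (0.838), seed markers (0.838), evening clock (0.845) and dusk genes (0.951). Test and mean differed in sign for evening clock, clock photoreceptors, cold and heat response, seed markers and dawn genes. CCA1 changed by -0.87 ± 0.20 (adjusted p = 0.0759) and passed with a pseudocount of 0.1 (0.0407) and with the replicate block (0.0378). The call of LNK3 ended with that pseudocount (0.0645), without a filter (0.145), with a mean of at least 5 FPKM (0.0719) and with only the groups compared (0.107), and that of LNK4 in the last 3 of these (0.128, 0.0726 and 0.0717). ZTL changed by 0.01 ± 0.13 (adjusted p = 0.986). Leaving out any single LL36 library reduced both the 243 higher and the 98 lower features, the lower ones least without Col-0 LL36 replicate 2. Of 27 named calls 20 held in all 8 fits. The call of LNK3 ended in 7 of them, that of LNK4 in 6, and those of IAA29 and SAUR21 in 4. Those of LHCB1.1, LHCB2.2 and LHCB2.1 ended in 3. LNK4 and these LHCB genes reached their highest adjusted p without ddcc LL36 replicate 1. LNK3 did so without Col-0 LL36 replicate 1 and SAUR21 without ddcc LL36 replicate 2.

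**Figure D3:**
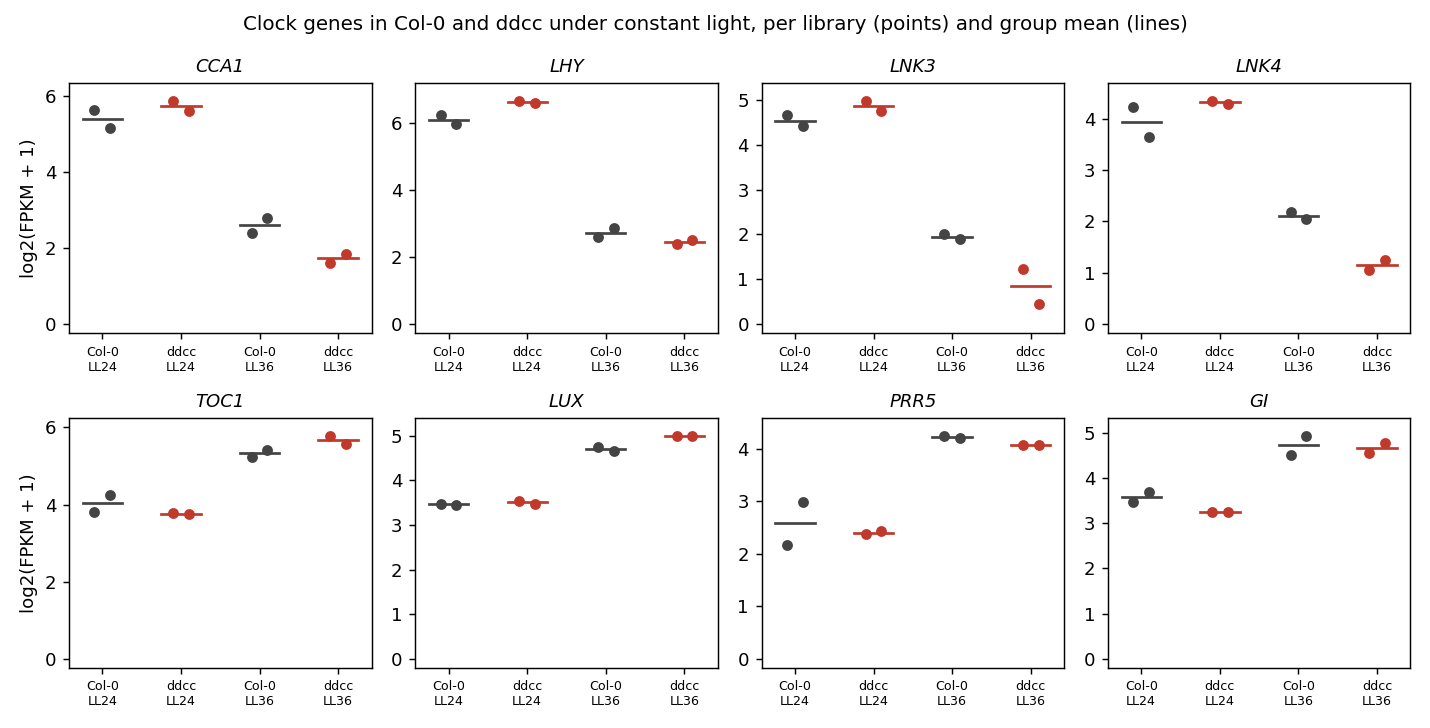
log2(FPKM + 1) of 8 clock genes in each Col-0 and ddcc library (points; lines are group means). LNK3 and LNK4 were called lower in ddcc at LL36; the other 6 genes were not called against Col-0 at either time.

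Over both times, 346 features were higher and 187 lower in ddcc. The lower count was 114 without Col-0 LL24 replicate 2, 93 and 99 without ddcc LL24 replicate 1 and replicate 2, and 102 without ddcc LL36 replicate 1; with a mean of at least 5 FPKM, 111 were higher and 97 lower. Of those higher at LL24, 207 were also higher at LL36, against 3.64 expected, and 33 were lower at both, against 0.341. As with Aza, the expected counts take the calls as independent, while both times share each feature's estimate of spread and the filter. This too can add to the excess. Of 467 called at either time, 401 changed in the same direction at both. Of the unnamed features 117 of 236 were higher and 1 lower, and of the long non-coding and antisense RNAs 29 of 227 were higher and 2 lower. The difference between the times reached the threshold for 0 features with limma (smallest adjusted p = 0.193), while 1650 had an unadjusted p below 0.05. With the replicate block, 11 features passed, 1 with a positive and 10 with a negative difference.

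Time in Col-0 under constant light again checks the labels. LHY fell by 3.37 ± 0.15 from LL24 to LL36 (SE, 2 libraries per group, adjusted p = 1.02e-05) and CCA1 by 2.79 ± 0.20 (adjusted p = 7.32e-05). TOC1 rose by 1.29 ± 0.16 (adjusted p = 0.00185), LUX by 1.23 ± 0.12 (adjusted p = 0.000432) and PRR5 by 1.65 ± 0.22 (adjusted p = 0.00308). GI rose by 1.14 ± 0.17 (adjusted p = 0.00507), opposite to its fall from ZT1 to ZT13 in Mock, and its call ended without Col-0 LL24 replicate 1. The experiments differ in light conditions and times of collection, so GI does not serve as a check of the labels. ELF4 changed by 0.91 ± 0.21 (adjusted p = 0.0528; 0.0215 with the replicate block and 0.0419 with a mean of at least 5 FPKM). In all, 281 genes were higher and 257 lower, a split that quantile normalization changed to 211 and 361. The calls became 111 higher and 114 lower without Col-0 LL24 replicate 1, 181 and 187 without Col-0 LL24 replicate 2, 123 and 159 without Col-0 LL36 replicate 1 and 543 and 265 without Col-0 LL36 replicate 2. With only the groups compared, which leaves 4 libraries, 11 genes were called: LHY stayed, while the calls of CCA1 (0.0580), TOC1 (0.132), GI (0.188), PRR5 (0.197) and LUX (0.0782) ended.

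The overlap of both experiments asks which genes respond to the compound and to the mutations. Of 17527 genes tested in both, 31 were higher over both times in each, against 3.07 expected (odds ratio 14.0, 95% interval 8.93 to 21.6, Fisher's exact test, adjusted p = 4.28e-22). The filters count treated and mutant libraries, so a gene silent in both controls is tested in both only where it rises in each. FWA, raised by Aza but low in ddcc, is left out in this way, and part of the excess can come from the filter. With a mean of at least 5 FPKM, 8 genes were higher and 3 lower in both. SDC rose by 3.06 ± 0.11 with Aza and by 4.68 ± 0.12 in ddcc, and QQS by 1.79 ± 0.11 and 2.93 ± 0.12. WRKY70 and PR2 were also higher in both. Lower in both were 10 genes, against 5.77 expected (adjusted p = 0.167), ROS1 among them (-0.76 ± 0.13 and -2.46 ± 0.14). Opposite directions were seen for 4 genes higher with Aza and lower in ddcc, against 3.96 expected (adjusted p = 0.801), and for 2 the other way, against 4.47 (adjusted p = 0.442): AT3G04320 and XTH20, named after their values were seen. The 4 were AT1G14250, DHAR1, AT2G18600 and AT4G01870, named likewise. The overlap of lower genes depends on the replicate block, with which 47 were lower in both, against 19.3 expected (adjusted p = 3.5e-08), and 57 higher, against 15.6 (adjusted p = 6.17e-17); opposite directions then numbered 24, against 15.8 (adjusted p = 0.0503), and 20, against 19.1 (adjusted p = 0.812). Leaving out 1 library gave 4 to 14 lower in both and 23 to 34 higher.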

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

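The tests of scaling, of single libraries and of the list differences below were read after the list results were seen, while the test of dawn and dusk genes was set before its result. Each group has 2 libraries, so no single library was tested for standing apart from its group. What stood out were lists whose response differed between the times, by camera with a preset correlation; none of these differences passed with an estimated correlation.

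With Aza, the change at ZT13 minus that at ZT1 was positive for defence (median 0.38, adjusted p = 2.08e-05), genes silenced by methylation (median 0.75, adjusted p = 0.00134), light harvesting (median 0.28, adjusted p = 0.0019) and DNA damage response (median 0.12, adjusted p = 0.0054). It was negative for DNA methylation machinery (median -0.22, adjusted p = 0.000764), clock photoreceptors (median -0.27, adjusted p = 0.00179) and root markers (median -0.31, adjusted p = 0.00285). With an estimated correlation the adjusted p of these lists lay between 0.177 and 0.828. Adjusted over the list alone, the difference was positive for 5 defence genes, 3 genes silenced by methylation and 3 DNA damage response genes, and for root markers positive for 1 and negative for 2; the other 3 lists had none. Single libraries ended 3 of these calls. Light harvesting gave 0.0644 without Aza ZT1 replicate 2, 0.0838 without Mock ZT13 replicate 2 and 0.143 without Aza ZT13 replicate 2. DNA damage response gave 0.116 without Mock ZT13 replicate 1 and 0.0747 without Aza ZT13 replicate 2, and root markers 0.0606 without Mock ZT13 replicate 1.

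In ddcc, the change at LL36 minus that at LL24 was negative for morning clock (median -0.38, adjusted p = 0.00158), light harvesting (median -0.42, adjusted p = 0.00158) and root markers (median -0.46, adjusted p = 0.0169), and positive for evening clock (median 0.27, adjusted p = 0.000291) and clock photoreceptors (median 0.12, adjusted p = 0.0477). The photoreceptor list shares FKF1 with the evening list; it gave 0.0561 with quantile normalization, 0.0673 without a filter, 0.0674 with a mean of at least 5 FPKM, 0.0546 with the replicate block and up to 0.828 without a library (Col-0 LL36 replicate 1), and also ended without Col-0 LL24 replicate 1 (0.0968), ddcc LL24 replicate 2 (0.123) and ddcc LL36 replicate 1 (0.137). Light harvesting gave 0.0614 without ddcc LL24 replicate 1 and 0.137 without ddcc LL36 replicate 1. Root markers gave 0.0722 without a filter, and 0.294, 0.0954, 0.195 and 0.306 without Col-0 LL24 replicate 1, ddcc LL24 replicate 2, Col-0 LL36 replicate 2 and ddcc LL36 replicate 1. Adjusted over the list alone, the difference was negative for 6 morning clock genes and 3 light harvesting genes, and the other 3 lists had none. Among the lists whose response was not called different between times, mean and test differed in sign in ddcc for DNA methylation machinery, DNA damage response, G2 to M phase, dusk genes and dawn genes, and mean and median with Aza for G2 to M phase. Some of those lists were called under an alternative: in ddcc cold and heat response with a pseudocount of 0.1 (0.0395), quantile normalization (0.0293) and the replicate block (0.0293) and defence with a mean of at least 5 FPKM (0.0499), and with Aza flavonoids with the replicate block (0.00718). Of those lists, evening clock and dawn genes had 1 positive member each with Aza adjusted over the list alone, and hypocotyl growth and defence 1 negative member each in ddcc.

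As lists, morning and evening clock genes moved apart in ddcc between the times, by camera with the preset correlation only. With an estimated correlation the adjusted p was 0.701 for the morning list and 0.239 for the evening list. Among their members none was called over all genes, and 6 morning genes and 0 evening genes passed adjusted over the list alone. Quantile normalization left the larger camera adjusted p of these lists at 0.00165. Since camera sets a list against all other genes, a shift common to a library largely cancels. This test therefore does not settle whether scaling had a part in the difference. A single library could carry part of it: the morning list gave 0.0774 without Col-0 LL36 replicate 2 and the evening list 0.0713 without Col-0 LL24 replicate 2, though no library ended both. A wider contrast between dawn and dusk genes in ddcc was tested on 662 genes that changed at least 4-fold with time in Mock; 62.1% moved that way, with a median of 0.10, and fry of limma, on the same fit, gave an unadjusted p of 0.0616, which leaves it undecided. An effect of the mutations, which the design names, stays open too, and with 2 times in constant light a shift of phase and a change of amplitude cannot be told apart.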

How the results depend on the processing

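The settings here were chosen before the data were examined, except that the mutated genes were left out of the DNA methylation machinery list in ddcc after seeing them, which moved none of its 3 results past the threshold. No called gene among those named changed direction in any setting. Their calls ended in 1 case with a pseudocount of 0.1, 1 with quantile normalization and 12 without a filter. They ended in 3 with a mean of at least 5 FPKM and 17 with only the groups compared. Leaving out 1 library at a time, summed over the libraries, ended more calls than any of these, as given per comparison above. Calls were gained in 1 case with a pseudocount of 0.1, 1 with a mean of at least 5 FPKM, 5 with the replicate block and 2 with only the groups compared. Among list tests, 36 of 108 were called with a preset correlation and 1 with an estimated one. Lists gained a call in 2 cases with a pseudocount of 0.1, 3 with a mean of at least 5 FPKM, 3 with quantile normalization, 4 with the replicate block and 55 with a library left out, and lost one in 0, 4, 2, 1 and 32, besides 4 without a filter. The only change of direction was that of the flavonoid list in ddcc at LL36, without Col-0 LL36 replicate 1 (adjusted p = 0.828, in a range from 4.25e-08 to 0.828 over the libraries left out). The causes were not tested unless given.

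Counts of called genes stayed within 1.5 times with a pseudocount of 0.1 and with quantile normalization. Without a filter, 1 gene passed for the difference of Aza between times, and Col-0 time gave 333. A mean of at least 5 FPKM, which tests fewer genes, gave 120 (Aza ZT1), 517 (Aza ZT13), 641 (Aza both times), 159 (ddcc LL24), 127 (ddcc LL36), 208 (ddcc both times) and 11 shared genes. Only the groups compared, with fewer libraries, gave 396 for Aza ZT13 and 11 for Col-0 time. A change of at least 2-fold, a stricter rule, gave 120 (Aza ZT1), 333 (Aza ZT13), 196 (Aza both times), 2428 (Mock time), 292 (ddcc both times) and 267 (Col-0 time).

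The labels do not say whether equal replicate numbers pair libraries, and with only 2 numbers this cannot be settled. As a hint, deviations from group means correlated positively in all 12 pairs of groups (r from 0.110 to 0.437, across genes). With a replicate block, 1571 genes were called for Aza ZT13 (747 higher and 824 lower), 704 for ddcc LL24 (518 and 186) and 627 for LL36 (383 and 244). The block gave 1094 for ddcc over both times (637 and 457), 11 for the ddcc difference between times, 1346 for Col-0 time and 104 shared.

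Leaving out 1 library at a time, where a lone library is taken to vary like the other groups, gave 26 to 303 genes for Aza ZT1, 373 to 898 for ZT13, 666 to 1371 over both times, 0 to 4 for the difference between times and 4751 to 7585 for Mock time. It gave 197 to 399 for ddcc LL24, 224 to 329 for LL36, 365 to 530 over both times, 0 to 4 for the difference between times, 225 to 808 for Col-0 time and 30 to 45 shared. The 4 differences came without Aza ZT13 replicate 2 and without ddcc LL24 replicate 1.

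The count model of DESeq2 was not run, since it needs counts. Of the list members, CLSY2, CLSY3 and CLSY4 were left out because their loci carry other symbols, and 4 transposable elements are in neither table. At these depths low genes are coarse: 1 fragment in a short gene moves its FPKM visibly, which the pseudocount of 1 damps.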

Other observations

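The tests of splits, of ENODL17 with Aza, of root tissue share and of single Mock libraries were chosen after the results were seen; those of genes near the mutated loci and of gene-poor windows were set before. With time as a term, the 8 Aza libraries make 34 splits of 4 against 4. Of these, 1, the real one, gave 1074 genes and the highest other gave 1. This share holds only if libraries are exchanged freely, also between times. The other splits mix treated and control libraries, which puts any effect of Aza into their residual spread. Their low counts therefore do not by themselves exclude chance. For ddcc the real split gave 485, again 1 of 34, and the highest other gave 1. Exchange confined both within equal replicate numbers and within each time would leave 8 splits, too few for a share under 0.05.

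ENODL17 fell to near 0 in ddcc and lies 4.97 kb from DRM1 in the TAIR10.1 annotation. A change linked to the mutated loci was tested on 153 genes within 100 kb of the 4 loci, without the 4 mutated genes and ENODL17: 3 were called over both times, against 406 of 19302 others (Fisher's exact test, p = 1). The 3 are AT5G15500 near DRM1 (0.62, adjusted p = 0.00688) and NIP1;2 (0.52, adjusted p = 0.0382) and AT4G19200 (-0.38, adjusted p = 0.0365) near CMT2. A share at or below that of the others had been set beforehand to count against linkage, but the shares differ within their spread and the window dilutes a change of a single neighbour, so after the result was seen this was taken as undecided. A loss of methylation that Aza brings about too is not settled either: ENODL17 changed by -0.35 ± 0.10 with Aza (adjusted p = 0.0852). These may both be at work and cannot be told apart, because the called shares do not differ beyond chance and the Aza change of ENODL17 lies above the bound of -0.5 by less than 2 SE.

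Root markers were lower with Aza at ZT13. A smaller share of root tissue alone, equal over root zones, would lower them by 1 factor. Their changes, from -1.82 for CASP1 to 1.26 for NRT2.1, differed beyond their errors (Cochran's Q, a chi-square approximation over n = 17 markers, p = 7.83e-31, and 2.14e-18 without NRT2.1). Part of Q can come from the log2(FPKM + 1) scale, on which 1 factor gives smaller changes at low values (PLT1, 1.33 FPKM in Mock). Markers with higher values differed too, CASP1 (36.3 FPKM) by -1.82 and PYK10 (1742 FPKM) by -0.34. This argues at most against root share as the only cause. A single Mock library is argued against, as the larger adjusted p without either was 5.77e-05 at the preset correlation, though with an estimated one the list was not called in the first place (adjusted p = 0.218). The Q test takes errors as independent, and a response within root cells to Aza stays open and untested.

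Genes raised in ddcc may lie where genes are sparse. Of 229 coding genes and other mapped features higher in ddcc over both times, 70 (30.6%) were in the 60 of 240 windows of 500 kb with the fewest coding genes, against 7.50% of the others (odds ratio 5.43, Fisher's exact test, p = 2.44e-24). The filter counts mutant and treated libraries, so features silent in the controls enter where they rise. Part of this odds ratio, and of the share for genes higher with Aza, can come from that, which was not tested. The share was 11.5% for genes lower in ddcc (adjusted p = 0.093), 10.1% for genes higher with Aza (adjusted p = 0.0279) and 6.71% for those lower (adjusted p = 0.646).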
